A study of Mus musculus with 4 samples.

How the data were processed

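Per the labels, the series profiled primary mouse hepatocytes treated with NEAA or left as control. Total RNA was extracted with Trizol and made into libraries with the NEBNext Ultra RNA kit, whose name in the labels does not include the directional variant. The submitters' processing notes name the genome builds GRCm38 and mm10, which are names of the same mouse assembly. The aligner, the transcript assembler, the program that estimated expression, its annotation release, its strand setting and any filter are not given in the sources used here. Without a stated strand setting, reads of overlapping genes on opposite strands, and of near-identical gene copies, may be split or shared in ways that the files do not show. The dose, composition and duration of the NEAA treatment are not given in the sources used here either.

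The authors deposited a file per sample with FPKM values (fragments per kilobase of transcript and mapped library size), the unit being given by the file names. The values were not whole, none was negative, and each row had a gene identifier without a transcript identifier. Rows were in the same order in all 4 files and were joined by position and identifier. A row is called a model here. Of the 19284 identifiers, 19170 were found in GENCODE M21, 29 Ensembl identifiers were not, and 85 identifiers with 141 rows belonged to loci outside the annotation, without coordinates. Gene symbols, gene classes and coordinates (1-based, GRCm38) came from GENCODE M21, and the synonym of Gm42418 from a RefSeq gene table of the same assembly. There were 15388 rows of lncRNA genes, 21761 of protein-coding genes and 73 of other genes, and 12287 rows were at 0 in all 4 samples. Because some models of genes that every cell uses, such as Gapdh, were at 0 in single samples, a 0 was taken as a listed value and not as absence. FPKM keep no depth, so counting intervals and detection limits could not be given, and low models rest on an unknown number of reads. FPKM are relative within a library, so a change in the share of abundant RNAs moves all other values.

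Samples were grouped by their labels, control and NEAA. Models with a mean of at least 1 FPKM over the 4 samples were kept, and log2(FPKM + 1) was fitted by group with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean trend in the variance). Tests were 2-sided, p-values were adjusted by Benjamini-Hochberg over the 6064 models, and a model was called at an adjusted p under 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low models, while means and SDs are of FPKM itself. An exact permutation test of 2 against 2 samples cannot go below p = 0.333, so the test pooled the spread over models. The replicate numbers were not used as pairs, since the labels do not say that they mark a shared animal or day.

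The lists were 27 sets of genes fixed before the data were examined. They covered paraspeckle components, well-known lncRNAs, snoRNA host lncRNAs, gluconeogenesis, glycolysis and glycogen, and proline and non-essential amino acid metabolism. They also covered ATF4 targets, amino acid transporters, urea cycle, SREBP targets, fatty acid oxidation, bile acid and drug metabolism, hepatocyte secreted proteins, acute phase, immediate early genes, ER chaperones, NRF2 targets, circadian clock, cell cycle, ribosomal proteins and dedifferentiation. The rest were mitochondrially encoded transcripts and markers of macrophages, endothelial cells, stellate cells and fibroblasts, cholangiocytes and red blood cells. The 19 lists with at least 5 tested models were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the 19 lists. Camera compares a list with all other models, and several models of a gene count separately in it. Counts adjusted over the list alone use limma p-values adjusted within that list and not across the lists. With the correlation estimated per list, 0 lists passed an adjusted p under 0.05.

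The rule for the genes named was fixed with the lists. It took 9 focus genes (Neat1, Malat1, Sfpq, Nono, Pspc1, Ppargc1a, Foxo1, G6pc and Pck1), and the 12 called models with a gene symbol and the largest log2 fold change in each direction whose groups did not overlap. It also took 5 lncRNA models in each direction, and up to 4 models of smallest p from each list. Clone-based names were counted as model names and not as gene symbols.

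The script was tested on simulated values for the 6064 models with 200 changed on purpose. It called 10.4% of those changed by 1 log2 unit, 67.2% of those changed by 2 and 80.3% of those changed by 3, with 2 unchanged models called. With a list raised by 1 log2 unit, 2 lists were called, the raised one and another. These values come from noise drawn separately for each model. With a single noise level for all models, 98.5%, 100% and 100% of those changed by 1, 2 and 3 log2 units were called. Recovery thus depends on the noise assumed. The alternatives tried were another pseudocount (0.1), no level filter, a filter of 5 FPKM, rescaling or quantile normalization of the samples, other variance models, a replicate block, leaving out each sample, other set tests and sums per gene. Tables were made with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures with matplotlib 3.10.9.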

Results

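RNA was profiled in primary mouse hepatocytes, the main metabolic cells of the liver, with or without added non-essential amino acids (NEAA), the amino acids that animal cells can make themselves. The submitters asked how NEAA affect long non-coding RNAs (lncRNAs). Their title also names proline, hepatic glucose production and the holding back of mRNA by paraspeckles, nuclear bodies built on the lncRNA Neat1. The 4 samples fell into 2 groups, control and NEAA, of 2 samples each. No label says whether they came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical. The deposited values are FPKM per transcript model without counts, so the sequencing depth is unknown. FPKM summed over all rows came to 73600.1 and 73377 in the control samples and to 65719 and 60942.0 in the NEAA samples. Gm26917 (chromosome 17, 39843013 to 39846341) and Gm42418 (chromosome 17, 39846958 to 39848788), a pair of annotated lincRNAs, held 51.7% ± 1.72 of that sum in control and 47.7% ± 2.36 in NEAA (SD, n = 2). RefSeq lists Gm42418 as a synonym of the ribosomal RNA pseudogene Rn18s-rs5, at 39846354 to 39848202.

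Each sample had values for 37363 models of 19284 gene identifiers, and 6064 models of 3658 genes reached a mean of 1 FPKM and were tested. Of these, 475 belonged to lncRNA genes, 5479 to protein-coding genes, 106 to loci outside the annotation and 4 to other genes. For 8991 of the 9265 protein-coding identifiers the number of models equalled the number of retained-intron transcripts in GENCODE M21, and for 9801 of the 9878 lncRNA identifiers it equalled the number of all annotated transcripts. The files pair a model with its gene and not with a transcript, so values below are per model. A protein-coding gene said to rise or fall stands for its model, which may be a retained-intron RNA. A value for a protein-coding gene is not its mRNA level. Log2 values of the control samples correlated with Pearson's r = 0.869 across models and those of the NEAA samples with r = 0.862, against 0.744 to 0.776 between samples of different groups. For a gene with several tested models, values are those of the model with the smallest p unless stated otherwise. Models are not independent replicates.

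In hepatocytes given NEAA, Neat1 fell from 63.4 ± 0.956 to 28.2 ± 0.299 FPKM (SD, n = 2). That call was near the threshold (limma adjusted p = 0.0481) and is lost in several settings, such as quantile normalization (limma adjusted p = 0.0547). The hosts of small nucleolar RNAs (snoRNAs), models of genes switched on by amino acid shortage through ATF4, and models of ribosomal protein genes fell as groups. Models of genes for cholesterol and fatty acid synthesis and for proteins that hepatocytes secrete rose as groups, and the lncRNA that contains the liver microRNA Mir122 rose from near 0. These 5 group calls rest on camera with a preset correlation of 0.01 between genes. Each is lost with an estimated correlation (camera adjusted p = 0.196 for each). They cover only the list genes with a tested model, 14 of 32 for lipid synthesis and 8 of 31 for secreted proteins. In all, limma called 176 of the 6064 models at an adjusted p under 0.05, 118 higher in NEAA (103 genes) and 58 lower (49 genes). The absolute log2 fold changes of the called models ran from 0.87 to 5.67 on the log2(FPKM + 1) scale, which understates the change of low models. The values of the groups did not overlap for 58.8% of the tested models, against 33.3% by chance for a single model. All models share the same 4 libraries, so a difference between libraries of any cause can separate many of them at once.

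Neat1 (ENSMUSG00000092274, GRCm38 chromosome 19, 5824708 to 5845478, minus strand, lincRNA) had 4 models, of which 1 passed the level filter. It changed by a log2 fold change of -1.14 (SE 0.14, limma adjusted p = 0.0481) and was lower in both NEAA samples, at 28.0 and 28.4 FPKM against 62.7 and 64.1. Which Neat1 transcript this model stands for could not be told, and paraspeckles themselves were not measured. Malat1 (ENSMUSG00000092341, chromosome 19, 5795690 to 5802672), the neighbouring lncRNA of nuclear speckles, measured 2360 ± 42.5 FPKM in control and 1580.2 ± 58.9 in NEAA, a log2 difference of -0.58 that did not pass (adjusted p = 0.0687), though it passed adjusted over the lncRNA models alone (adjusted p = 0.0301). Among the paraspeckle components fixed beforehand, 2 of 34 models fell and 32 did not pass, and the same 2 fell adjusted over the list alone. They were Neat1 and the RNA-binding protein gene Taf15, from 4.48 ± 0.238 to 1.59 ± 0.0310 FPKM. Dazap1 measured 5.53 FPKM in control and 2.98 in NEAA, and Matr3 3.82 and 2.35, without passing. The list as a whole did not pass by camera (adjusted p = 0.0950), which compares it with all other models. It passed by fry, which does not (fry adjusted p = 0.0116). None of the 4 models of Nono or the 2 of Pspc1, which code for core paraspeckle proteins, was called, with log2 fold changes from -0.35 to 0.22. The deposited values hold no model under the symbols Sfpq, Ppargc1a, Foxo1 or G6pc, so these genes could not be tested.

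Other lncRNAs moved both ways. Of the 475 lncRNA models, 21 rose (18 genes) and 16 fell (14 genes), and 42 rose and 46 fell when adjusted over the list alone, that is over the lncRNA models. The split depended on the setting, with 5 higher and 13 lower at a filter of 5 FPKM and 13 higher and 6 lower after rescaling to a sum of 1000000. The lncRNAs that rose most by the rule were AC157910.3, 1810064F22Rik, AC117816.1 and Gm43305. AC157910.3 (chromosome 18, 65244287 to 65252621, plus strand) contains Mir122 (65248861 to 65248926, same strand), the most abundant microRNA of hepatocytes. Its models measured 0.150 and 0.0630 FPKM in control against 7.60 and 7.06 in NEAA, and 0 and 0 (listed at 0) against 8.31 and 8.45. AC117816.1 (chromosome 19, 31950084 to 31952361) rose from 1.28 ± 0.0846 to 10.9 ± 1.33 FPKM, and Gm43305 (chromosome 14, 54292443 to 54297456) from 1.07 ± 0.138 to 9.72 ± 0.962. A model of 1810064F22Rik (chromosome 9, 22196963 to 22213860), annotated as antisense and overlapping Zfp872 on the other strand, rose from 0.144 ± 0.154 to 5.12 ± 0.699 FPKM. As the strand setting of the counting is not given, its reads cannot be told from those of Zfp872.

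The lncRNAs that fell most were Gm19619, Snhg8, 2410006H16Rik, Mir17hg and AL805899.1. Mir17hg (chromosome 14, 115042879 to 115046727), the host of the growth-promoting miR-17 cluster, fell from 14.2 ± 0.213 to 4.18 ± 0.0102 FPKM. AL805899.1 (chromosome 4, 88909855 to 88938521), which contains Mir31, fell from 6.92 ± 0.579 to 2.0 ± 0.0648 FPKM. Gm19619 (chromosome 5, 91257571 to 91283421), which overlaps no other annotated gene, fell from 3.46 ± 0.0187 to 0.254 ± 0.0214 FPKM. 2410006H16Rik (chromosome 11, 62602877 to 62604807), which contains the snoRNAs Snord49a, Snord49b and Snord65, fell from 47.7 ± 0.321 to 14.3 ± 1.80 FPKM. Among the fixed list of snoRNA host lncRNAs, 47 of 53 models had a negative log2 fold change, with a median of -0.48, and the list fell (camera adjusted p = 2.7e-05). That call is lost with an estimated correlation (adjusted p = 0.196). In it 2 models fell, and 9 fell adjusted over the list alone. The called ones were 1 of 3 tested models of Snhg8 (chromosome 3, 123507552 to 123508404), from 21.8 ± 3.25 to 5.72 ± 0.484 FPKM, and Epb41l4aos (chromosome 18, 33794892 to 33795986), from 26.5 ± 1.79 to 10.6 ± 0.242. A model of Zfas1 measured 26.7 ± 1.23 and 9.89 ± 1.70 FPKM and a model of Gas5 22.0 ± 1.27 and 4.87 ± 1.95, without passing (adjusted p = 0.0518 and 0.0548), though both passed adjusted over the lncRNA models alone (adjusted p = 0.0194 and 0.0210). The list of well-known lncRNAs also fell (camera adjusted p = 0.00914, and adjusted p = 0.201 with an estimated correlation). That call is lost too under quantile normalization (adjusted p = 0.0587), without the level filter (0.163) and without control 1 (0.0504). In it 2 of 31 models fell, Mir17hg and Neat1, and 5 fell adjusted over the list alone. The list includes Gm26917, which measured 28738 FPKM in control and 22801.5 in NEAA. A model of Lncpint measured 2.85 ± 0.287 and 0.574 ± 0.298 FPKM. It did not pass (limma adjusted p = 0.0549), though it passed adjusted over the lncRNA models alone (0.0212). Of the 10 tested models of Lncpint, 5 had a positive and 5 a negative log2 fold change.

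**Figure D1:**
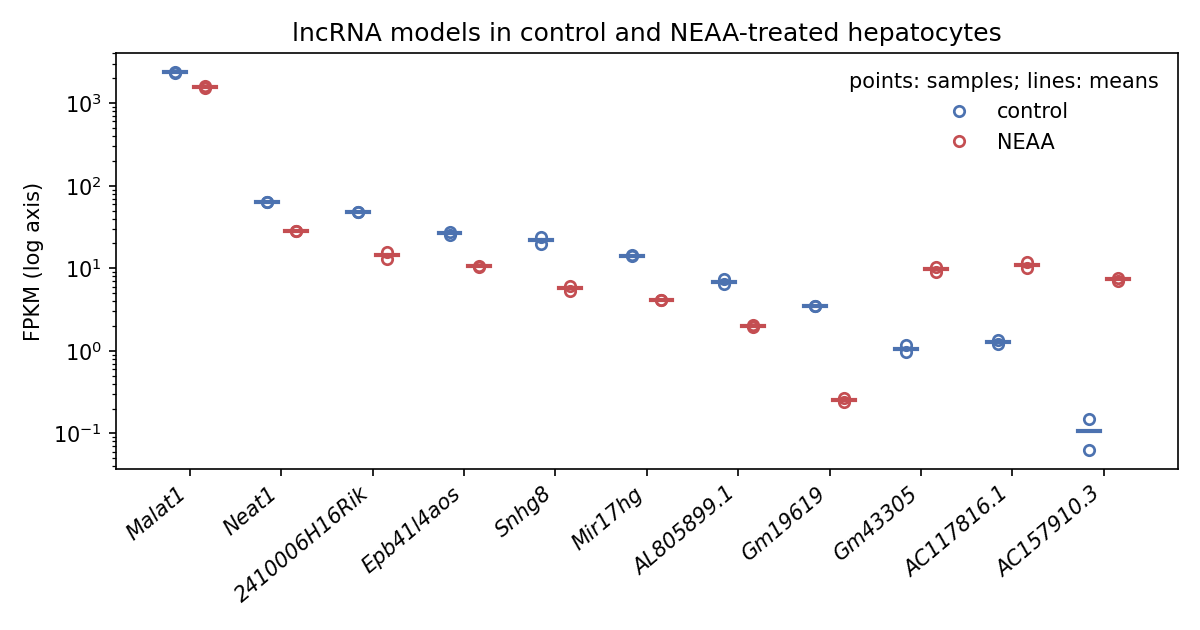
FPKM of 11 lncRNA models (log axis) in the control (blue) and NEAA (red) samples, with a circle per sample and a line at the mean of the 2 samples. Neat1 drops from 63.4 to 28.2 FPKM, and AC157910.3, the Mir122 host, goes from 0.107 to 7.33, while the Malat1 difference did not pass over all models.

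Among the models that rose most was that of Adh1. This model, of a gene for an alcohol dehydrogenase of hepatocytes, rose from 0.528 ± 0.0149 to 14.3 ± 0.669 FPKM. Its log2 fold change was 3.33 (SE 0.12, limma adjusted p = 0.0231). Cyp2c70, which makes muricholic bile acids, rose from 1.19 ± 0.482 to 20.2 ± 2.31 FPKM, and Selenbp2, a selenium-binding protein gene, from 0.0754 ± 0.00617 to 5.94 ± 0.376. Both belong to families of similar genes, which could share reads. All 7 models of Cp, the secreted copper protein ceruloplasmin, had higher means in NEAA and 5 were called, the largest change being from 36.0 ± 0.790 to 198 ± 52.0 FPKM. Both models of the iron regulator Hfe rose, one of them from 2.46 ± 0.502 to 19.9 ± 3.13 FPKM. A model of the transcription elongation factor gene Supt5 rose from 0.194 ± 0.0820 to 28.3 ± 0.432 FPKM, the largest positive log2 fold change by the rule at 4.62. A model of Sec11a, a subunit of signal peptidase, rose from 1.24 ± 0.116 to 13.7 ± 3.18 FPKM. The DNA repair gene Rad51b rose from 0.602 ± 0.0453 to 8.42 ± 0.263 FPKM, and Cdca3, which acts at entry into mitosis, from 0.268 ± 0.0256 to 5.43 ± 0.567. Some were listed at 0 in control. Zfp981, of the large family of zinc finger genes, measured 0 and 0 against 22.7 and 14.9 FPKM. Hmgn2, which has many pseudogenes, measured 0 and 0 against 8.58 and 13.0, and Shcbp1 measured 0 and 0.0231 against 4.95 and 4.08. A 0 in these files can be a failed estimate, so no fold is given.

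Among the models that fell most, both of Slc7a11, the cystine importer, went down, from 5.49 ± 0.347 to 0.645 ± 0.0972 FPKM and from 5.04 ± 0.374 to 0.706 ± 0.127. Models of Slc4a11, a membrane transporter, fell from 6.19 ± 0.546 to 0.341 ± 0.0202 and from 6.61 ± 1.80 to 0.434 ± 0.277 FPKM. Both models of Hmga2, a chromatin protein gene of growing cells, fell, the one with the larger log2 fold change from 5.18 ± 0.628 to 0.555 ± 0.0776 FPKM, and Dhrs9, a retinol dehydrogenase, from 4.50 ± 0.213 to 0.111 ± 0.0245. Zfyve16, an endosomal protein gene, fell from 4.23 ± 0.0742 to 0.207 ± 0.0263 FPKM. Wac fell from 7.35 ± 0.50 to 1.08 ± 0.0139, and a model of Mia2, needed for export of large cargo from the endoplasmic reticulum (ER), fell from 22.8 ± 0.775 to 4.57 ± 1.18 FPKM. A model of Nop56, a core protein of snoRNA particles, fell from 7.39 ± 0.0529 to 1.09 ± 0.313 FPKM, but the sum over its models did not pass (log2 fold change -0.79, limma adjusted p = 0.331). A model of the phospholipase gene Plcb3 measured 4.67 and 4.48 FPKM in control against 0.313 and 0. The most negative log2 fold change, -5.67, was that of a model of the glycolytic gene Gapdh, at 129 and 58.6 FPKM in control against 0 and 2.0 in NEAA. The 2 other tested models of Gapdh had higher means in NEAA without passing. A model of the ribosomal protein gene Rps12 measured 4.01 and 6.38 FPKM against 0 and 0. Gapdh and Rps12 have many near-identical pseudogenes and their values are uncertain. The 24 models of these opposite ends had limma adjusted p-values from 0.0231 to 0.0474.

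**Figure D2:**
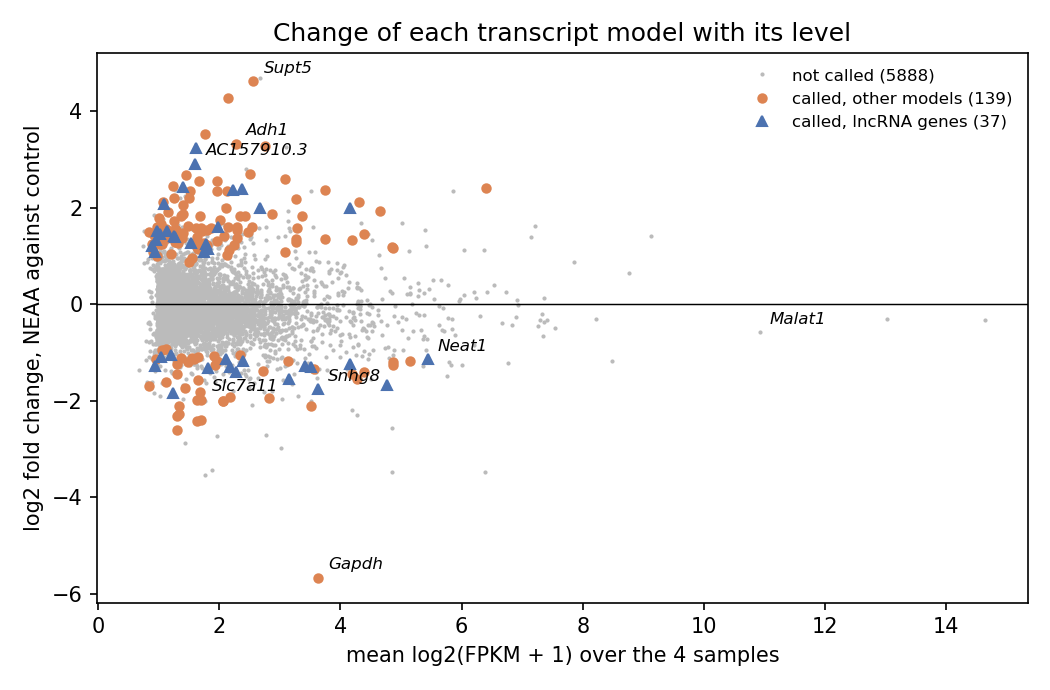
Log2 fold change, NEAA against control, of each of the 6064 tested models (vertical axis) against its mean log2(FPKM + 1) over the 4 samples (horizontal axis). Triangles are the 37 called models of lncRNA genes, filled circles the other 139 called models and grey dots the 5888 models not called; Gapdh, at -5.67, lies lowest.

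The list of the amino acid shortage response fell with NEAA. Its tested models covered 15 of 39 genes. All 19 tested models of ATF4 targets had a negative log2 fold change, with a median of -0.48, and the list fell (camera adjusted p = 4.4e-05, and adjusted p = 0.196 with an estimated correlation). In it 3 models fell and 8 fell adjusted over the list alone. The 3 were both models of Slc7a11 and Cth, the enzyme that makes cysteine from cystathionine, from 4.94 ± 0.448 to 1.46 ± 0.157 FPKM. Slc38a2, an importer of neutral amino acids, measured 8.86 ± 0.0472 and 4.50 ± 0.211 FPKM and did not pass (adjusted p = 0.0626). Of 16 amino acid transporter models, 1 rose and 3 fell, and 1 rose and 4 fell adjusted over the list alone. Beside those of Slc7a11, Slc7a1, the importer of cationic amino acids, fell from 2.80 ± 0.381 to 0.745 ± 0.0473 FPKM, and Slc6a13, a carrier of taurine and GABA, rose from 0.414 ± 0.137 to 2.96 ± 0.0163. That list did not pass by camera (adjusted p = 0.262) but did by fry (adjusted p = 0.0276).

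In the list of proline and non-essential amino acid metabolism 9 of 18 models had a positive and 9 a negative log2 fold change. In it 4 models rose, and 5 rose and 4 fell adjusted over the list alone. The glutamate dehydrogenase gene Glud1 rose from 4.66 ± 0.115 to 15.9 ± 1.12 FPKM, and the alanine aminotransferase gene Gpt2 from 1.82 ± 0.124 to 7.58 ± 0.341. Amt, of glycine cleavage, rose from 0.556 ± 0.0566 to 2.79 ± 0.516 FPKM, and glutamine synthetase, Glul, from 0.355 ± 0.123 to 2.20 ± 0.267. The list did not pass (camera adjusted p = 0.332), and its median of -0.08 and mean of 0.13 differ in sign. Of 11 gluconeogenesis models only Gpt2 rose, and 2 rose adjusted over the list alone. Gpt measured 0.889 FPKM in control and 2.42 in NEAA, and the models of the pyruvate carrier gene Mpc1 measured 0.661 and 1.35 in control and 1.92 and 2.97 in NEAA, without passing. This list did not pass either (camera adjusted p = 0.190, upward, with a mean of 0.24 and a median of -0.21). By fry, which does not compare a list with other genes, the gluconeogenesis list passed (adjusted p = 0.0310). Pck1, which codes for the rate-setting enzyme of glucose production, had 2 models below the level filter. The higher of them measured 0.0185 and 0.0333 FPKM in control against 1.06 and 0.182 in NEAA.

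The tested models of the lists of lipid synthesis genes and hepatocyte products rose as groups. They covered 14 of 32 and 8 of 31 genes. Of 19 models of SREBP targets, genes of cholesterol and fatty acid synthesis, 18 had a positive log2 fold change, with a median of 0.99, and the list rose (camera adjusted p = 1.3e-08, and adjusted p = 0.196 with an estimated correlation). In it 4 models rose, and 11 rose adjusted over the list alone. Insig1, which restrains SREBP processing, rose from 0.596 ± 0.0136 to 3.88 ± 0.421 FPKM. Fdps rose from 0.611 ± 0.0569 to 2.86 ± 0.0435 FPKM and Hmgcs1 from 1.29 ± 0.129 to 4.35 ± 0.0584, both genes of the mevalonate pathway. All 10 models of hepatocyte secreted proteins had a positive log2 fold change, with a median of 1.12, and the list rose (camera adjusted p = 1.4e-06, and adjusted p = 0.196 with an estimated correlation). In it 2 models rose, and 8 rose adjusted over the list alone. Apoe rose from 0.441 ± 0.0225 to 3.09 ± 0.674 FPKM and Itih3 from 18.4 ± 0.627 to 42.8 ± 0.378. Trf measured 13.7 and 35.4 FPKM and Ahsg 2.15 and 5.63, without passing.

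Other metabolic and secretory lists also rose as groups. Their tested models covered 6 of 29 fatty acid oxidation genes, 12 of 23 glycolysis and glycogen genes and 10 of 21 ER chaperone genes. The fatty acid oxidation list rose (camera adjusted p = 0.00480, and adjusted p = 0.223 with an estimated correlation), with 0 of its 10 models called and 2 higher adjusted over the list alone. Creb3l3 measured 0.552 FPKM in control and 2.36 in NEAA, Acadm 1.01 and 1.91, and Acadvl 1.08 and 2.01. The glycolysis and glycogen list rose (camera adjusted p = 0.00167, and adjusted p = 0.219 with an estimated correlation), although its 1 called model, that of Gapdh, fell, and the call is lost at a filter of 5 FPKM (adjusted p = 0.381). Adjusted over the list alone, 5 models rose and 1 fell. A model of Ldha measured 4.29 and 12.9 FPKM and its other one 2.48 and 2.37, Tpi1 1.23 and 3.28, and Pgk1 1.51 and 3.31. The ER chaperone list rose (camera adjusted p = 0.00121, and adjusted p = 0.196 with an estimated correlation), with 0 of 19 models called and 2 higher adjusted over the list alone. Xbp1 measured 6.65 ± 0.414 FPKM in control and 15.2 ± 0.0146 in NEAA (adjusted p = 0.0501), Calr 1.46 and 3.68, Pdia6 1.45 and 3.26, and Hsp90b1 1.06 and 1.89.

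The cell cycle list rose and the ribosomal protein list fell, with few or none of their models called. Their tested models covered 8 of 26 and 36 of 45 genes. The cell cycle list rose with a median of 0.60 (camera adjusted p = 7.8e-04, and adjusted p = 0.196 with an estimated correlation). Both of its 2 called models, of 12, belonged to Ccnb1, cyclin B1, and went from 0.111 ± 0.0597 to 4.16 ± 0.944 and from 0.132 ± 0.106 to 2.42 ± 0.0755 FPKM. Adjusted over the list alone, 3 models rose, and Rrm2 measured 0.419 and 1.66 FPKM without passing. Summed FPKM of macrophage markers measured 3.29 ± 0.303 in control and 5.91 ± 1.15 in NEAA, and those of cholangiocyte markers 0.481 ± 0.0320 and 1.36 ± 0.216. Each higher sum rests on a single gene, Cd14 for macrophages and Pkhd1 for cholangiocytes. Without Cd14 the 10 other macrophage models summed to 1.01 and 1.01 FPKM in control against 0.589 and 1.78 in NEAA. Endothelial markers measured 12.4 ± 1.53 and 11.3 ± 1.73, stellate and fibroblast markers 5.13 ± 0.621 and 4.04 ± 0.0640, and red blood cell markers 0.0200 ± 0.0120 and 0.0410 ± 0.00800. These sums are given as values and were not tested. Of 83 models of cytosolic ribosomal proteins 72 had a negative log2 fold change, with a median of -0.35, and the list fell (camera adjusted p = 9.9e-05, and adjusted p = 0.196 with an estimated correlation). By limma, 0 of them were called over all models and 0 adjusted over the list alone, with 27 at an unadjusted p under 0.05, all lower, and the list call is lost among genes with a single model (adjusted p = 0.317). Rpl7 measured 98.6 ± 11.5 and 54.2 ± 0.660 FPKM, Rpl18 35.6 and 18.6, Rpl15 8.91 and 4.14, and Rps4x 3.65 and 1.99. These genes have many pseudogenes that could share reads.

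Of the remaining lists, none that was tested passed by camera. By fry the NRF2 target list (adjusted p = 0.0212) and the circadian list (adjusted p = 0.0116) did. Among immediate early genes 1 of 5 models was called, Fosl1, which fell from 3.09 ± 0.564 to 0.498 ± 0.0722 FPKM, and 2 rose and 1 fell adjusted over the list alone. Dusp1 measured 18.7 and 32.1 FPKM and Fosl2 2.89 and 2.09 (list adjusted p = 0.847 by camera, which pointed up while the median of -0.08 and the mean of -0.07 were negative). Among NRF2 targets 2 of 26 models fell, both of Slc7a11, and 4 fell adjusted over the list alone (list adjusted p = 0.332). Sqstm1 measured 3.35 and 1.36 FPKM without passing. No model was called in the acute phase list (adjusted p = 0.103), where Cxcl1 measured 14.0 and 19.7 FPKM, Ccl2 8.18 and 11.3, and Lcn2 30.8 and 35.9. The same held for the circadian list (adjusted p = 0.180), where Nr1d2 measured 3.48 and 1.86 and Bhlhe40 5.41 and 4.22. It held too for the dedifferentiation list (adjusted p = 0.306), where Flna measured 9.80 and 5.81, Vim 3.04 and 4.97, and Cd44 5.08 and 3.21. Adjusted over the list alone, 0 models passed in each of these 3 lists, and 0, 1 and 4 had an unadjusted limma p under 0.05. Lists with fewer than 5 tested models were not tested. They were urea cycle, where Glul rose and Slc25a15 measured 1.20 and 1.61 FPKM, and bile acid and drug metabolism, where Adh1 rose, Gsta3 measured 0.517 and 1.81 and the models of Cyp27a1 1.92 and 1.35 in control and 2.84 and 1.37 in NEAA. The macrophage list kept only Cd14, at 2.28 ± 0.307 and 4.72 ± 0.310 FPKM without passing over all models (limma adjusted p = 0.0717). Adjusting over a list of 1 model leaves the p-value as it is (limma unadjusted p = 0.00463). The endothelial list kept Stab1, at 1.38 and 0.882, and Egfl7, whose models had log2 fold changes from -0.38 to 0.11. No model of the stellate and fibroblast, cholangiocyte or red blood cell lists reached the level filter, and the files hold no model of the mitochondrially encoded list, so it says nothing about RNA quality. Adjusted over the list alone, 1 model rose in the urea cycle list, 2 rose in the bile acid and drug list and 0 changed in the endothelial list.

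**Figure D3:**
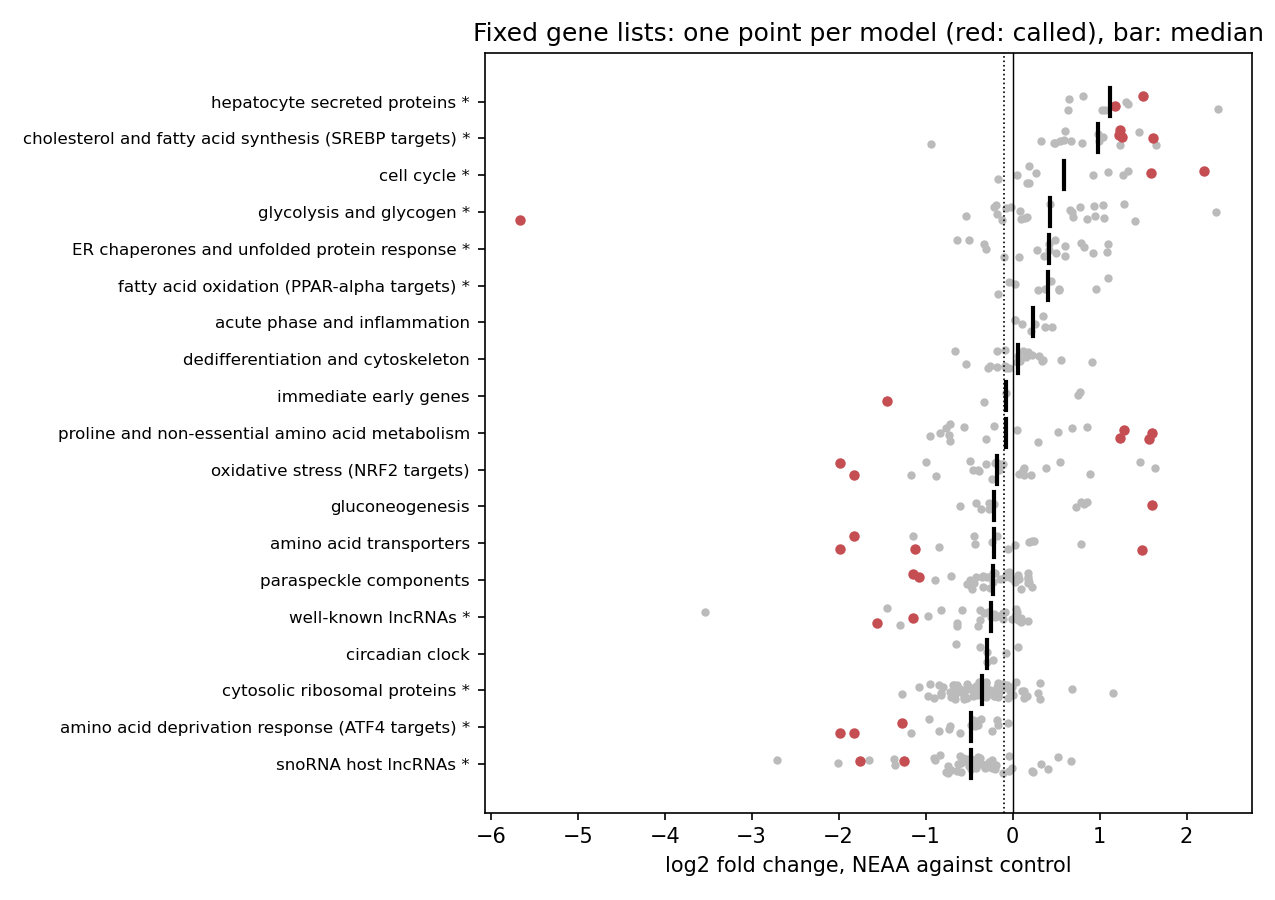
Log2 fold change, NEAA against control (horizontal axis), of each tested model in the 19 fixed lists tested. Points are models, red where limma called them and grey otherwise; black bars are list medians, from -0.48 for snoRNA hosts to 1.12 for hepatocyte secreted proteins, the dotted line is the median of all tested models (-0.09) and a star marks the 10 lists that passed with the preset correlation.

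With 2 samples per group these calls are close to the limit of what the design can give: leaving out any 1 of the 4 libraries, control 1, control 2, NEAA 1 or NEAA 2, leaves 1 residual degree of freedom and 0 models called by limma, with 1076, 1102, 1227 and 1248 at an unadjusted p under 0.05. All 176 called models kept their direction each time, which is largely expected of models picked for being called in the same samples. Without the level filter 0 of 25076 were called by limma, with 4000 at an unadjusted p under 0.05. Rescaling every sample to a sum of 1000000, which also makes the pseudocount smaller beside the values, moved the median log2 fold change of all tested models from -0.09 to 0.07 and the calls to 90 higher and 20 lower, and took Neat1 to -0.95 with an adjusted p of 0.0735; rescaling to the mean sum moved the median to 0.05 and gave 151 higher and 40 lower, with Neat1 at -0.93 (adjusted p = 0.0762).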

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

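The gene sums, the rescalings to the mean sum, the restriction to models above 0 in all samples and that to genes with a single model were chosen after seeing the data; the other settings were fixed before the data were examined. Each of the 176 called models kept its sign in every setting that tested it as a model. In the gene sums 151 of 152 genes did. All settings reuse the same 4 samples, and the models were picked for being called in them. Kept directions, here and below, are therefore largely expected and add no separate support. The number past the threshold depended on the setting. Adjusted over the lncRNA models alone, 88 lncRNA models passed in place of 37. With the replicate block, limma called 0 models and 0 lncRNA models (1323 models at an unadjusted p under 0.05), and Neat1 stayed at -1.14 (adjusted p = 0.155). The block leaves 1 residual degree of freedom, the equal numbers mark nothing in the labels, and the deviations of same-numbered samples correlated at -0.002, so they were not treated as paired. Leaving out 1 sample at a time also leaves 1 degree, the lone sample being assumed to vary like the other group. It gave 0 models and 0 lncRNA models each time, while all 176 kept their direction with an unadjusted p under 0.05, a Neat1 value from -1.155 to -1.125 (adjusted p from 0.139 to 0.200) and 9 or 10 lists. With no level filter 25076 models were tested, and 0 models and 0 lncRNA models were called (4000 at an unadjusted p under 0.05), with Neat1 at -1.14 (adjusted p = 0.114). A filter of 5 FPKM gave 100 models (46 higher and 54 lower), 18 lncRNA models (5 higher and 13 lower) and 4 lists, 5 of the 10 called lists being too small to test, and a pseudocount of 0.1 gave 23 lncRNA models. Rescaling every sample to a sum of 1000000, which also makes the pseudocount smaller beside the values, gave 110 models, 19 lncRNA models (13 higher and 6 lower) and Neat1 at -0.95 (adjusted p = 0.0735). Quantile normalization took Neat1 to -0.96 (adjusted p = 0.0547), rescaling to the mean sum to -0.93 (0.0762) with 191 models, and rescaling without Gm26917 and Gm42418 to -1.04 (0.0563). Over all settings the adjusted p of Neat1 ran from 0.0162 to 0.200. Sums per gene gave 475 genes (282 higher and 193 lower), 92 lncRNA genes, and Neat1 at -1.14 with the lowest of these p-values. Genes with a single model gave 1 list, the ATF4 targets, 8 of the 10 being too small to test. With a correlation estimated per list 0 lists passed, and fry, which does not compare a list with other genes, passed 15. Where no reason is given, the cause was not tested. Of 877 values of the 53 named called models over 18 settings, 534 stayed past the threshold, 343 kept only the direction and 0 reversed. The unknown depth limits all low models.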

Other observations

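Genes outside the fixed lists are named in this paragraph and the next after their values were seen. At least 1 model of each of 5 centromere and cell division genes, picked from the called models, rose with NEAA. Both tested models of Cenpa, the centromere histone gene, rose, one of them from 0.705 ± 0.0535 to 5.03 ± 0.0664 FPKM (SD, n = 2). Both of Prc1, a protein of the spindle midzone, rose, one from 0.161 ± 0.0206 to 2.67 ± 0.00206 FPKM. Hjurp, which loads Cenpa onto chromosomes, rose from 4.80 ± 0.0764 to 11.3 ± 0.682 FPKM in 1 of 2 models. Ect2, needed for cytokinesis, rose from 0.315 ± 0.0477 to 2.12 ± 0.390 FPKM in 1 of 2 models, and Oip5 from 0.287 ± 0.00886 to 1.73 ± 0.130. The limma adjusted p-values of these called models reached at most 0.0481.

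All 5 tested models of Chka, choline kinase alpha (chromosome 19, 3851773 to 3894369), fell, with log2 fold changes from -1.45 to -1.17. All 3 tested models of the antisense lncRNA 1110002L01Rik (chromosome 12, 3403878 to 3427011) fell, with log2 fold changes from -1.30 to -1.29. Models of the nucleolar protein genes Mybbp1a and Ncl fell, from 32.0 ± 0.681 to 10.2 ± 0.116 and from 12.3 ± 0.328 to 4.83 ± 0.264 FPKM, 1 model being called of 6 and of 4. In contrast to Cth, models of Cbs, which makes cystathionine, and Gss, the glutathione synthetase gene, rose, from 1.71 ± 0.351 to 8.62 ± 1.76 and from 0.628 ± 0.0328 to 3.22 ± 0.579 FPKM, in 1 of 2 models each. Tsc22d3, a gene known to be induced by glucocorticoids, rose from 1.60 ± 0.171 to 5.89 ± 0.0196 FPKM. At loci outside the annotation, 15 models of 13 loci rose and 0 fell by limma, with 37 of 106 at an unadjusted p under 0.05, and the log2 fold changes of the called ones ran from 1.37 to 2.55. Adjusted over these models alone, 21 rose and 8 fell.

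The tests on the higher lncRNA models and on the cell cycle sums against 0 were chosen only after the results were seen, and the predictions of the others were written before. Neat1 was lower in the NEAA samples. Every sample was rescaled to one sum without the adjoining loci Gm26917 and Gm42418. The Neat1 log2 fold change stayed at -1.04 (95% t interval -1.45 to -0.62), though the call was lost at a limma adjusted p of 0.0563. This goes against a change in those loci as the whole cause. Their share of the summed FPKM was lower in NEAA, at 47.7% against 51.7%. That sum covers only the deposited models, so the share of these loci in the whole library is not known. The sum without them was also lower in NEAA, at 33062 FPKM against 35515 in control. The sum over the 4 Neat1 models moved by -1.14 (-1.48 to -0.81), which goes against reads moving between them. The other 474 lncRNA models had a median of -0.11 (bootstrap 95% interval -0.17 to -0.04), above the bound of -0.5 set for a general loss. A halving at their median level of 1.74 FPKM would give -0.55. The median thus goes against a general halving of these models. The 66 of at least 5 FPKM had a median of -0.37 (-0.59 to -0.12). That interval reaches the bound but stays above -0.86, the Neat1 value plus 2 standard errors. These 66 went both ways, 18 up and 48 down with an SD of 1.06, so their distance from Neat1 is within their spread. A loss among the more abundant lncRNAs may account for at least part of the drop. Malat1 was at -0.58 (limma adjusted p = 0.0687, and 0.0301 over the lncRNA models alone). A response to NEAA or a difference between cultures or library preparations, which the labels do not describe, stays open too.

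The cell cycle list was higher in the NEAA samples. Summed over models, its 11 genes had a median log2 fold change of 0.65 (bootstrap 95% interval 0.19 to 1.57), which reaches below the bound of 0.5 set beforehand, but the 8 genes with a tested model had a median of 0.58 (0.19 to 1.63), above 0, which goes against reads moving between the deposited models as the whole cause, as does the sum of Ccnb1, the gene of both called models, at 2.72 (limma adjusted p = 0.00654), and the sums passed as a list with the preset correlation (camera adjusted p = 6.6e-04) and not with an estimated one (0.236). Markers of macrophages, endothelial cells, stellate cells and cholangiocytes had a median of 0.0277 over 46 models (-0.01 to 0.10), under the bound of 0.5 set for dividing cells of another type. That bound was found unusable only after the result was seen, since the markers lay at a median of 0.255 FPKM, where a doubling gives 0.27 on this scale, so the test was set to undecided. Dividing cells of another type, reads moving between these models and mRNA, and a response of hepatocytes to NEAA may each account for the rise and stay open.

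Called models often shared their gene with others. Where reads had moved between models of a gene, the other models would go the opposite way, but for 109 of 123 called models, 88.6% (exact Clopper-Pearson 95% interval 81.6% to 93.6%), the sum of the others moved the same way. Of the models not called, 70.8% did so too, so shared movement is common here. The interval for the called models treats them as separate trials, which models of the same gene are not, so it may be too narrow. Gapdh was an exception, with a model that fell and 2 with higher means. Reads moving between these models and the mRNA of the same gene may still account for part of the calls, since mRNA models were not analysed here.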
